A study of Mus musculus with 13 samples.

How the data were processed

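Single cells of MMTV-PyMT mammary tumours and of lung metastases were profiled with Drop-seq and Nextera XT tagmentation, per the labels' protocols. The deposited values are raw counts of UMIs per gene symbol and cell barcode, 1 library per file: the files hold whole numbers without normalization, and that they are UMI counts follows from the Drop-seq protocol in the labels. STAR, FastQC and the builds GRCh37.p13, hg19 and GRCm38.p5 are named in the submitters' processing notes without their roles, and the counting program, annotation and cell filter are not stated. The 13 files held 91203 barcodes and 38104 gene symbols in all, and 508480 to 4394442 UMIs per library.

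Cells were kept with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Doublets were scored per library with Scrublet (scanpy 1.11.5, expected share 5%), and where its automatic threshold marked under 0.5% of cells the top 5% of scores were removed. The 10539 kept cells were normalised, reduced to 2000 variable genes and 30 principal components, joined to 15 neighbours and clustered with Leiden (leidenalg 0.10.2, resolution 1, seed 1). Clusters were named from marker genes of 24 classes, and names end in "-like" because they rest on markers alone. The marker genes were fixed beforehand, but the thresholds for naming were set after the clusters were seen: luminal (tumour epithelial) with at least 3 markers in at least 40% of cells, other classes with at least 3 markers 2-fold higher and in at least 10% of cells. Libraries were grouped by the labels. Replicate numbers were not used to pair libraries, as the labels do not state that they mark shared animals or days.

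Shares of kept cells were compared with exact two-sided permutation tests of group means (the smaller tail doubled), adjusted by Benjamini-Hochberg over classes with a mean share of at least 0.5% in either group. Gene tests used sums of UMIs over the cells of a class in each library with at least 20 such cells, in edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test; Benjamini-Hochberg, threshold 0.05) under R 4.3.3. The 3 mammary groups shared a fit, and lung_metastasis was fitted with PyMT_primary. The biological coefficient of variation was 0.422 for tumour epithelial-like cells of mammary libraries (84 to 1977 cells each), 0.477 with the lung libraries (from 22 cells) and 0.439 for macrophage or monocyte-like cells (24 to 217 cells, 10 libraries, PyMT_primary replicate 1 left out). The p-values measure spread between samples. The SE of a log2 fold change is its absolute value divided by the square root of edgeR's F statistic, so it adds nothing to the test. CPM of Akt1, Akt2 and Gapdh, of Csn2 at its limit and of lung stages are raw. So are those of immune markers, of Esr1 where immune cells are set against tumour cells, and of the cluster that matched no class. Other CPM use TMM library sizes. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, with Benjamini-Hochberg over the 24 lists tested. Intervals are exact binomial at 95%, a count of 0 allows up to 3 counts of the total, and both cover counting error only.

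The design, marker genes of cell classes, 29 gene lists, the rule for named genes and 17 alternatives were fixed before the data were examined. The rule named genes past the threshold with at least 20 CPM in the higher group and the same direction in every library of the smaller group, up to 12 each way. Where under 10 passed, it added the 5 with the smallest p each way, the targeted genes, and the members of each called list with the smallest p, of which 2 are given. For the lung stages it named the 10 largest ratios each way with at least 50 UMIs and 100 CPM in the higher library. Symbols of unnamed genes were left out of the gene tests' names, and some genes the rule named are left out because they are withheld for evaluation. A further 7 alternatives were chosen after seeing the data: merging barcodes 1 base apart, leaving out genes with near-identical copies, a processing class term, the same with a barcode term, class B libraries alone, leaving out libraries with over 5% haemoglobin, and leaving Esr1 out of the lists. A gene was held to have a near-identical copy when at least 25% of the 31-base words of its last 400 transcript bases occurred elsewhere in GRCm38 transcripts (1305 genes). Processing class was set by Gapdh above or below 50 CPM, and the barcode term by whether barcodes with an undetermined last base occur.

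The gene tests were tested on simulated data with 200 genes changed. In tumour epithelial-like cells, 61.5% of 4-fold and 7.58% of 2-fold changes were called for Akt1_deleted against PyMT_primary (8103 genes), 61.9% and 12.1% for Akt2_deleted against PyMT_primary (8118 genes), 39.7% and 3.03% for Akt2_deleted against Akt1_deleted (8118 genes), and 7.81% and 0% for lung_metastasis against PyMT_primary (8789 genes). In macrophage or monocyte-like cells, 82.1%, 69.7% and 68.2% of 4-fold changes were called for the mammary comparisons in the same order (990, 983 and 983 genes). The changed genes were a far larger share of the genes tested there, which eases the Benjamini-Hochberg threshold. These percentages are therefore not comparable with those of tumour epithelial-like cells, and fewer changes would be called where few genes change. DESeq2 1.42.0 served as the other tool. Gene tests of neutrophil-like, fibroblast-like and T cell-like cells were left out, since too few libraries held 20 such cells, and Akt1 and Akt2 were under the count filter in macrophage or monocyte-like cells. Matplotlib 3.10.9 drew the figures.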

Results

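Mouse mammary tumours driven by the MMTV-PyMT transgene, in which polyoma middle T is made under a mammary promoter, were profiled with Drop-seq, a droplet method that counts unique molecules (UMIs) of transcripts per cell. The 13 libraries fell into 4 groups: 5 of primary mammary tumours (PyMT_primary), 3 of mammary tumours after systemic deletion of Akt1 (Akt1_deleted), 3 after systemic deletion of Akt2 (Akt2_deleted) and 2 of lung metastases (lung_metastasis). The deletions were induced in the whole animal with tamoxifen and ERT2Cre, a recombinase fused to the ligand-binding part of the oestrogen receptor. The group labels do not say whether PyMT_primary animals received tamoxifen or carried ERT2Cre. Differences of the deletion groups from PyMT_primary were therefore not separated from effects of either. The mammary tumours were taken 3 weeks after a tumour could be felt. Replicate 1 of the lung group was a micro-metastasis and replicate 2 a macro-metastasis, 1 library of each stage.

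The deposited libraries held 508480 to 4394442 UMIs each, and 119 to 2363 cells per library were kept, 10539 in all. Of these, 8027 cells were luminal epithelial, the tumour class, 974 were macrophage or monocyte-like, 439 fibroblast-like and 377 T cell-like. Smaller classes were alveolar macrophage-like (62 cells), neutrophil-like (50), endothelial-like (48) and erythroid-like (19). A group of 57 cells resembled B cells but had more plasma cell than B cell genes among its top genes, and 486 cells matched no class; neither was compared. Median depth was 813 to 1224.5 UMIs per kept cell and library, so a single cell showed only its abundant transcripts, and the tests below used sums over the cells of a class in each library.

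Akt1 (GRCm38 chr12:112653821-112674884) and Akt2 (chr7:27591552-27640826) encode kinases that pass on growth factor and insulin signals, and their transcripts were lower in the tumours deleted for them. Akt1 averaged 13.3 ± 6.88 CPM (UMIs scaled to a fixed total; SD, n = 3) over the kept cells of Akt1_deleted and 38.1 ± 9.42 CPM (n = 5) in PyMT_primary, and all 3 libraries lay below the lowest PyMT_primary library at 26.7 CPM. Akt2 averaged 11.99 ± 3.09 CPM (n = 3) in Akt2_deleted and 22.7 ± 7.37 CPM (n = 5) in PyMT_primary, again without overlap. The exact two-sided permutation p was 0.0357 for each, the smallest that 3 against 5 libraries allow. Between the deletions, Akt1 was 1.86-fold higher and Akt2 2.14-fold lower in Akt2_deleted than in Akt1_deleted, each with an exact permutation p of 0.1, the smallest that 3 against 3 allow. Akt1 in Akt2_deleted was 24.7 ± 5.62 CPM, and its difference from PyMT_primary had an exact permutation p of 0.0714. Transcripts remained in every deleted library, from 5.82 CPM of Akt1 and 8.502 CPM of Akt2 upward; the counts are taken at the 3′ end, so transcripts that lost an exon elsewhere would still be counted, and the values check the sample labels but do not measure how complete the deletion was. In tumour epithelial-like cells alone, Akt1 was 10.1 ± 4.97 CPM in Akt1_deleted against 32.0 ± 7.96 CPM in PyMT_primary (exact permutation p 0.0357), and Akt2 was 11.9 ± 2.10 CPM in Akt2_deleted against 20.02 ± 5.96 CPM (exact permutation p 0.0714).

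**Figure D1:**
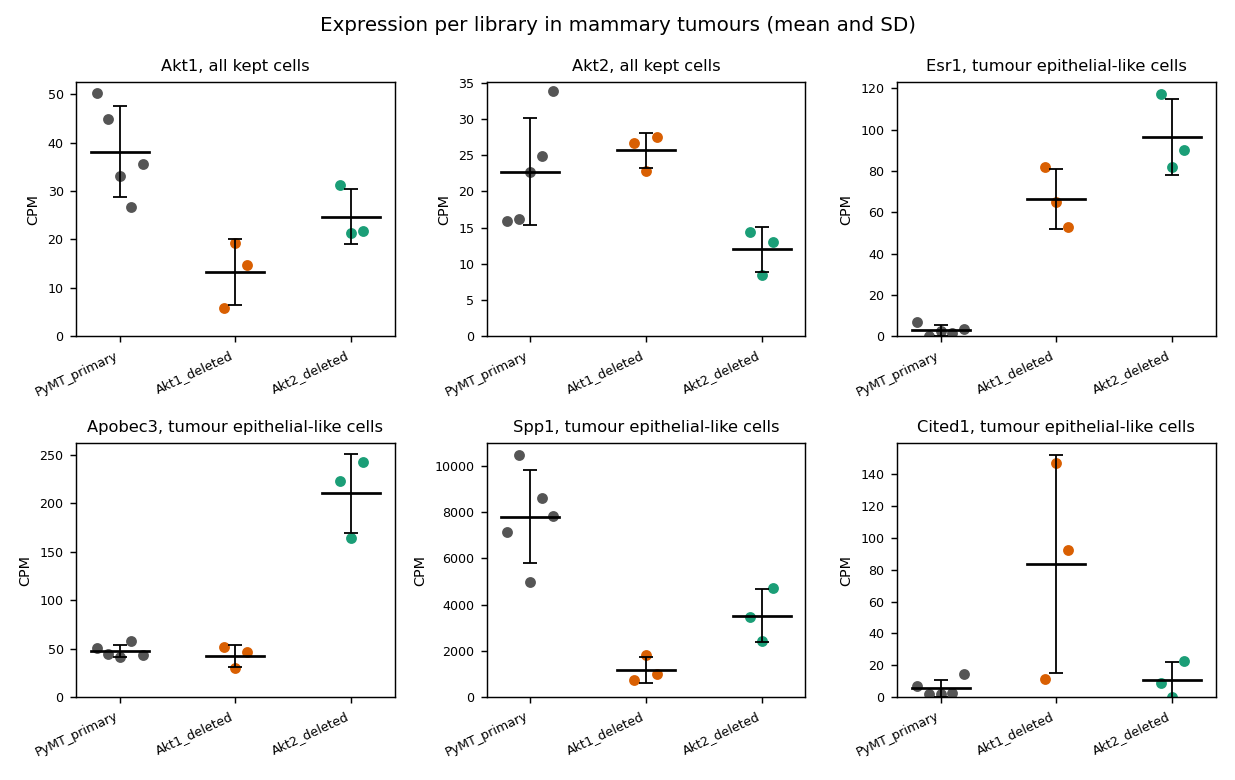
CPM per library (points) with the group mean and SD (black) for Akt1 and Akt2 over all kept cells and for Esr1, Apobec3, Spp1 and Cited1 in tumour epithelial-like cells, in PyMT_primary (n = 5), Akt1_deleted (n = 3) and Akt2_deleted (n = 3). Esr1 lies at 52.7 to 117 CPM in the deletion groups and at 0 to 6.68 CPM in PyMT_primary.

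T cell-like cells, which carry the T cell receptor genes Trac, Trbc1 and Trbc2, made up 11.8 ± 7.41% (SD, n = 3) of the kept cells in Akt1_deleted and 0.312 ± 0.373% (n = 3) in Akt2_deleted. The lowest Akt1_deleted library, at 3.36%, lay above the highest Akt2_deleted library, at 0.725%. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow, and 0.6 after Benjamini-Hochberg adjustment over 6 classes. PyMT_primary had 2.50 ± 2.60% T cell-like cells (n = 5, 0.0473 to 5.33%), which 2 of 3 Akt1_deleted libraries exceeded (exact permutation p 0.107, adjusted 0.429). Luminal epithelial cells made up 72.3 ± 19.5% in PyMT_primary, 70.0 ± 15.01% in Akt1_deleted and 76.1 ± 6.80% in Akt2_deleted. Macrophage or monocyte-like cells, marked by C1qa, Apoe and Csf1r, made up 13.9 ± 13.2%, 11.8 ± 5.53% and 13.6 ± 10.6%. Fibroblast-like cells fell from 8.38 ± 7.28% in PyMT_primary to 4.37 ± 1.40% and 3.33 ± 1.75%. None of these differences had an adjusted exact permutation p below 0.429, and the smallest unadjusted exact permutation p against PyMT_primary was 0.107. Neutrophil-like cells were at 1.56 ± 1.37% in Akt2_deleted, with 0 of 2363 cells in replicate 1. Replicates 2 and 3 had 3 of 119 and 3 of 138 cells, and 21.02% and 26.6% haemoglobin UMIs. None were seen in Akt1_deleted (0 of 335 to 0 of 833 cells, which allows up to 0.896% in the smallest library). No mammary library held enough neutrophil-like cells for a gene test.

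**Figure D2:**
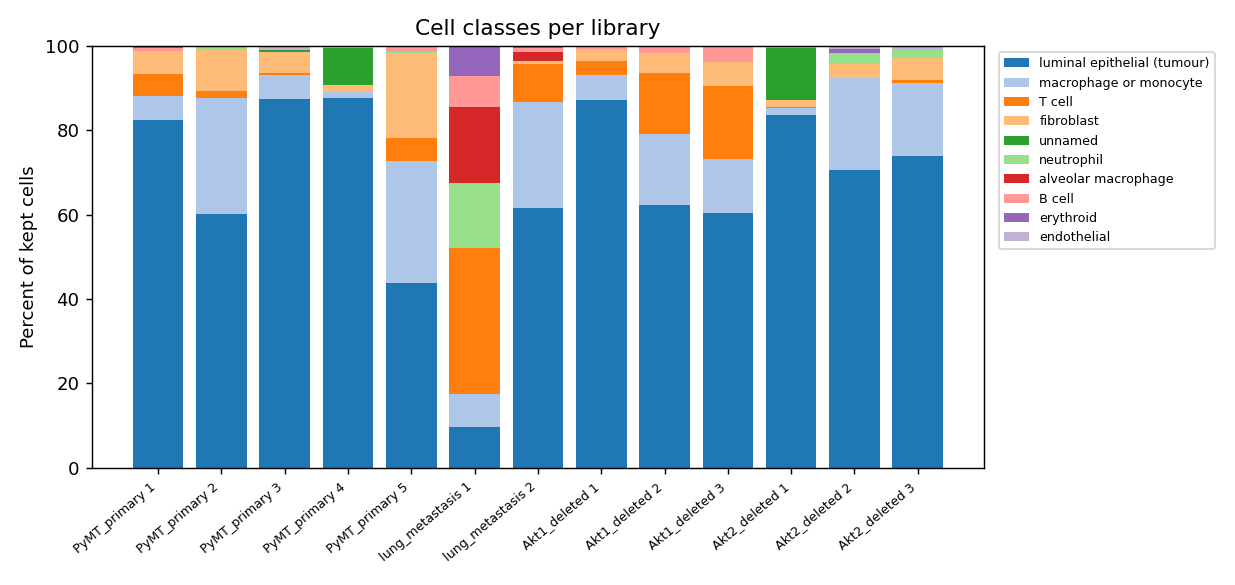
Percent of kept cells in each class, as stacked bars, for each of the 13 libraries. Luminal epithelial cells form the largest class in every mammary library (43.9 to 87.6%), and T cell-like cells are most frequent in the lung library of the micro-metastasis (34.6%).

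Whether Akt1 deletion changed the tumour cells was asked by comparing the epithelial-like cells of Akt1_deleted with those of PyMT_primary. This comparison does not separate the deletion from tamoxifen or ERT2Cre. Esr1 (chr10:4611593-5005614), the oestrogen receptor gene, was the gene past the threshold: it rose from 2.83 ± 2.54 CPM (n = 5) to 66.5 ± 14.7 CPM (n = 3), a log2 fold change of 4.86 ± 0.43 (SE) with an adjusted p of 0.00103 in edgeR's quasi-likelihood test, and every Akt1_deleted library lay above every PyMT_primary library. The ERT2Cre transgene carries part of the same coding sequence. Spp1, which encodes the secreted protein osteopontin, had the next smallest p and did not pass: it fell by 2.73 ± 0.41 (SE) on the log2 scale, from 4962 to 10490 CPM over the PyMT_primary libraries to 719 to 1804 CPM (adjusted p 0.0994 in edgeR). Cited1, a partner of the oestrogen receptor in luminal cells, rose by 4.20 ± 0.88 on the log2 scale but ranged from 11.1 to 147 CPM over the 3 libraries (adjusted p 0.354 in edgeR). The cytokine signalling inhibitor Socs2 (log2 fold change 1.49), the splicing factor Hnrnpf (2.16), the transcription factor subunit Taf13 (1.06) and the mitochondrial assembly factor Lyrm7 (3.12) also rose without passing. The haem enzyme gene Alad (-1.35), the scaffold gene Sash1 (-1.59), the matrix gene Mgp (-2.50) and the phosphatase gene Ptprg (-1.51) fell without passing. Akt1 itself fell by 1.63 ± 0.41 (adjusted p 0.426). In all, 1 of 8453 tested genes passed, 681 had an unadjusted p under 0.05, and DESeq2 called 19. Without PyMT_primary replicate 5, 64 genes passed. The cells lay in different proportions in the clusters of the class. One led by Wfdc18 and Fxyd3 held 4.69% of them in PyMT_primary on average and 27.8% in Akt1_deleted (15.4 to 48.1%, highest in replicate 1). Its PyMT_primary libraries ranged from 1.51 to 11.9%, highest in replicate 5. One led by Scgb2b27 and Lalba held 20.2% and 5.77%, and its PyMT_primary range of 2.65 to 39.3% spans the Akt1_deleted values. Shifts between clusters were not separated from changes within them, here or in the lists below.

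Lists of genes fixed beforehand were tested in the same cells with camera. The hormone-sensing luminal list rose (median log2 fold change 1.85, 6 genes, adjusted p 2.02e-09), led by Esr1 and Cited1. Without Esr1, whose counts were not separated from those of the transgene, its median was 0.685 (adjusted p 0.0122). The cholesterol synthesis list rose (median 0.39, 15 genes, adjusted p 0.00104), led by Fdps (log2 fold change 1.60) and the sterol carrier gene Stard4 (1.09). The MHC class I list, which presents peptides to T cells, rose as well (median 0.42, 12 genes, adjusted p 0.00213), led by H2-D1 (1.18) and H2-K1 (0.89). A different strain background was not separated from the MHC lists, here or below, since the ratio of the class II genes H2-Eb1 and H2-Aa varied between libraries. The interferon response list had a median of 0.40 (22 genes, adjusted p 0.0318), and its members with the smallest p went both ways, Ifit3 at 1.23 and Parp14 at -0.92. Ribosomal protein genes had a median of 1.16 (81 genes, adjusted p 5.00e-28), led by Rpl5 (2.89) and Rpl31 (2.27), and the nuclear respiratory chain list a median of 0.10 (77 genes, adjusted p 0.0148), led by Uqcrb (1.09) and Uqcrq (0.94). Adjusted over the list alone, 3 hormone-sensing genes passed, against 1 over all genes tested, and 0 of the other 5 lists' genes did in edgeR. Camera's preset correlation between genes is low, and with the correlation estimated from the libraries none of these 6 calls held (adjusted p 0.124 to 0.777). Fdps, H2-D1, Ifit3 and Uqcrb have near-identical copies, so their counts are uncertain, and with such genes left out the interferon (adjusted p 0.0564) and respiratory chain lists (0.052) did not pass.

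Libraries fell into 2 kinds that crossed the groups, called processing classes here although the cause was not tested: in PyMT_primary replicates 1 to 4 and the micro-metastasis, Gapdh, an abundant glycolysis gene, had 5.29 to 8.07 CPM over kept cells (class A), and in the other 8 libraries 192 to 697 CPM (class B). Transcripts of genes with near-identical copies elsewhere in the genome made up 7.22 to 9.60% of UMIs in class A and 12.4 to 15.9% in class B. Every deletion library is of class B, as is PyMT_primary replicate 5, which had 35.6 CPM of Akt1, 33.8 CPM of Akt2 and 5.33% T cell-like cells. With a class term in the model, the log2 fold change of Esr1 in Akt1_deleted was 4.17 and that of Spp1 -2.74, with an adjusted p of 1 in edgeR for each, since that fit compares the deletion with replicate 5 alone. The median of the ribosomal protein list was then 0.04 (adjusted p 0.679) and that of the respiratory chain list -0.11 (adjusted p 0.149). The hormone-sensing (1.62), cholesterol (0.63), MHC class I (0.75) and interferon (1.35) lists had medians above 0 and adjusted p values of 2.97e-04 or below. Lists not called without the term were then called lower: mesenchymal (-1.12, adjusted p 5.96e-05), neutrophil activation (-0.97, adjusted p 6.93e-04), NFkB target (-0.66, adjusted p 0.00108) and mitosis genes (-0.38, adjusted p 0.0111). With a barcode term as well the hormone-sensing median was 0.47 (adjusted p 0.0426), the other 3 lists stayed higher, mesenchymal genes stayed lower (-1.49, adjusted p 6.89e-05) and the other 3 of those called lower did not pass. ER stress genes were then called higher (0.58, adjusted p 0.00616), and milk genes lower (-1.53, adjusted p 8.71e-07; -0.06 and 0.472 with neither term). The list calls with these terms, here and below, use camera's preset correlation and were not run with an estimated one, with which no list passed in any comparison without the terms.

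The same question was asked of Akt2, with the same limit. Esr1 rose from 2.83 ± 2.54 CPM (n = 5) to 96.5 ± 18.2 CPM (n = 3) in the epithelial-like cells of Akt2_deleted, a log2 fold change of 5.41 ± 0.43 (SE; adjusted p 3.21e-04 in edgeR). Apobec3 (chr15:79891659-79915906), which encodes a cytidine deaminase that restricts retroviruses, rose from 47.5 ± 6.28 to 210 ± 40.9 CPM (log2 fold change 2.14 ± 0.22, adjusted p 0.00218), and for both genes all 3 libraries lay above all 5 PyMT_primary libraries. The fatty acid transporter gene Slc43a3 was nearly absent from Akt2_deleted, at 0.741 ± 1.28 CPM against 39.9 ± 18.5 CPM in PyMT_primary, and the collagen gene Col16a1 fell by 1.93 on the log2 scale, but neither passed (adjusted p 0.0587 in edgeR for both). The respiratory chain gene Ndufs5 (log2 fold change 2.20, adjusted p 0.0587), the haem oxygenase gene Hmox1 (2.32), Hnrnpf (2.11), Ccdc12 (1.12) and Pisd-ps1 (1.24) rose without passing. The annexin gene Anxa1 (-0.96) and the small nucleolar RNA Snord118 (-2.41) fell without passing, as did Akt2 (-0.62 ± 0.35, adjusted p 0.813). In all, 2 of 8453 genes passed, 611 had an unadjusted p under 0.05, and DESeq2 called 29. Without PyMT_primary replicate 5, 58 genes passed. Ndufs5 has near-identical copies, so its counts are uncertain. With the class term, Esr1 (4.71) and Apobec3 (2.27) kept their direction with an adjusted p of 0.814 in edgeR.

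Among the lists, milk and alveolar differentiation genes fell in Akt2_deleted (median log2 fold change -1.25, 13 genes, adjusted p 1.57e-04), led by the amino acid oxidase gene Lao1 (-5.04) and the milk protein gene Lalba (-1.42). The cells of the class lay in different proportions in its clusters. One led by Scgb2b27 and Lalba held 20.2% of them in PyMT_primary on average (2.65 to 39.3%) and 7.44% in Akt2_deleted. One with Ltf, Saa1 and Saa2 at the top held 12.8% (3.17 to 20.8%) and 3.27%, and one led by Npy 33.6% in Akt2_deleted replicate 1. Shifts between clusters were not separated from changes within them. Factors that attract myeloid cells fell (median -0.64, 10 genes, adjusted p 0.0342), led by the acute phase genes Saa3 (-5.12) and Saa1 (-2.18). Mitochondrially encoded genes fell (median -0.66, 8 genes, adjusted p 0.00979), led by mt-Nd1 (-0.87) and mt-Nd4 (-0.69). The hormone-sensing list was called higher by camera (adjusted p 0.00979) although its median was -0.17 and its mean 0.73, since Esr1 rose and Gata3 fell by 0.52; without Esr1 it did not pass (-0.378, adjusted p 0.599). Ribosomal protein genes had a median of 0.83 (adjusted p 4.12e-18), led by Rpl5 (2.66) and Rpl29 (3.96). Saa3 and Rpl29 have near-identical copies and are uncertain. Adjusted over the list alone, 1 milk gene and 1 hormone-sensing gene passed, and 0 ribosomal, mitochondrial or myeloid factor genes did in edgeR. None of these 5 calls held with an estimated correlation (adjusted p 0.711). With the class term, the milk (median -0.82, adjusted p 3.51e-06) and myeloid factor lists (-0.70, adjusted p 0.00766) stayed lower, ribosomal protein genes turned lower (-0.28, adjusted p 0.00131), and the mitochondrial (-0.39, adjusted p 0.269) and hormone-sensing lists (-0.35, adjusted p 0.42) no longer passed. With the barcode term as well, the myeloid factor list did not pass either (-0.51, adjusted p 0.124), and the milk list stayed lower (-1.60). The class term also called lists that were not called without it: interferon response genes turned higher (0.66, adjusted p 0.00432, against -0.22 without the term; 0.89 with the barcode term, adjusted p 2.78e-04), and cholesterol synthesis genes were higher (0.30, adjusted p 0.0444). Mitosis (-0.57, adjusted p 3.51e-06), S phase (-0.35, adjusted p 0.032), hypoxia (-0.57), glycolysis (-0.56), respiratory chain (-0.26) and neutrophil activation genes (-1.22) were lower, of which mitosis, hypoxia and neutrophil activation genes stayed so with the barcode term.

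**Figure D3:**
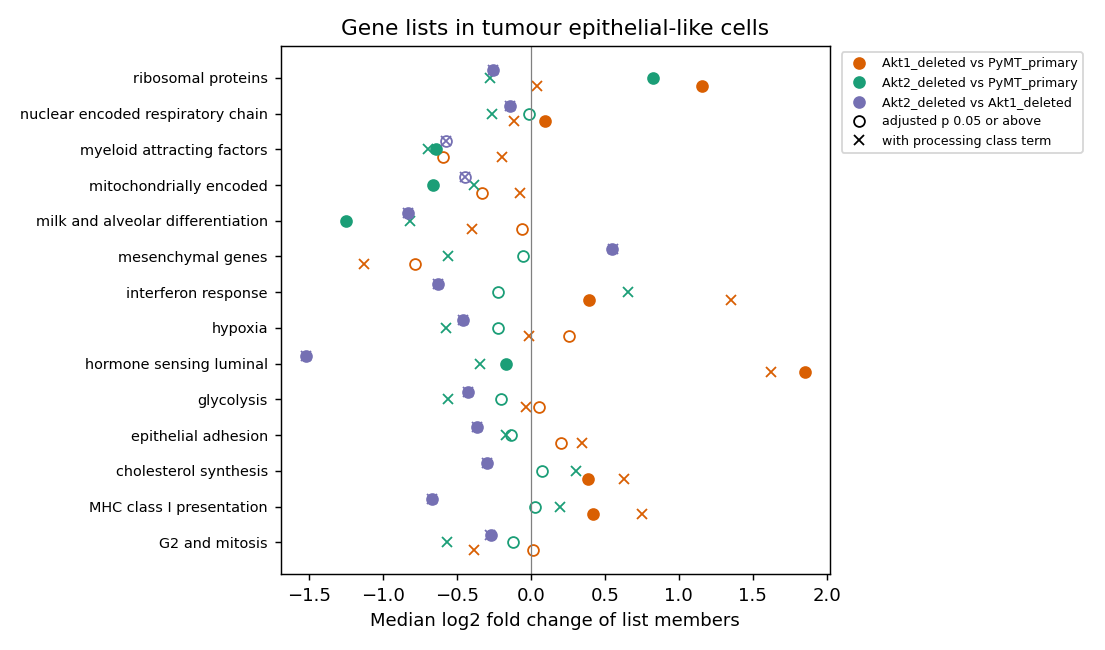
Median log2 fold change of the members of each gene list in tumour epithelial-like cells (circles, filled where camera's adjusted p was under 0.05) for the 3 mammary comparisons, and the same median with a processing class term in the model (crosses). The ribosomal protein median moves from 1.16 to 0.04 for Akt1_deleted and from 0.83 to -0.28 for Akt2_deleted, both against PyMT_primary.

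The deletions, both of class B, were compared with each other directly in the shared fit of the 3 mammary groups, which also holds class A libraries. Apobec3 was the gene past the threshold, at 210 ± 40.9 CPM (n = 3) in Akt2_deleted and 42.5 ± 11.2 CPM (n = 3) in Akt1_deleted (log2 fold change 2.29 ± 0.26, SE; adjusted p 0.0156 in edgeR), without overlap. Irs2, an insulin receptor substrate gene, was 85.3 ± 4.37 CPM in Akt2_deleted and 29.8 ± 7.59 CPM in Akt1_deleted (log2 fold change 1.54 ± 0.27), without overlap, and did not pass (adjusted p 0.182). It is a FOXO target, and the list of such targets was not called (median -0.03, 7 of 14 genes above 0, adjusted p 0.739 in camera). Slc43a3 was lower in Akt2_deleted (-4.34 ± 0.71, adjusted p 0.182), as were Anxa1 (-1.21), Col16a1 (-1.41) and the ER stress gene Manf (-1.06). Ndufs5 (2.47), the cytidine deaminase gene Cda (2.56), Snhg12 (1.93) and Rabgef1 (1.45) were higher. Akt1 (1.43) and Akt2 (-0.99) went in the directions of the labels without passing (adjusted p 0.779 and 0.979). In all, 1 of 8453 genes passed, 392 had an unadjusted p under 0.05, and DESeq2 called 9. The count of 1 fell to 0 in edgeR when any of 5 of the 6 deletion libraries was left out (all but Akt2_deleted replicate 2). It was also 0 in a fit of the 2 deletion groups alone.

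Milk genes were lower in Akt2_deleted than in Akt1_deleted (median log2 fold change -0.83, adjusted p 0.00304), and Csn1s2a fell by 5.16. Csn2, which encodes beta-casein, had 0 of 2835560 UMIs in Akt2_deleted, which allows up to 1.06 CPM (raw). With TMM library sizes it ranged from 1.011 to 681 CPM over the Akt1_deleted libraries, the lowest of which did not exceed that limit. Csn2 was therefore at least 353-fold lower than the Akt1_deleted mean and at least 293-fold lower than the PyMT_primary mean. These bounds hold for the group means and not for every library. Most of the 2835560 UMIs are from Akt2_deleted replicate 1, and without it the limit was 7.99 CPM and the bounds 46.8-fold and 38.8-fold. Without PyMT_primary replicate 5 the bound against PyMT_primary was 42.6-fold. With class and barcode terms the median of the milk list was -0.45 (adjusted p 0.00236), and it was about as low against PyMT_primary in Akt1_deleted (-1.53) as in Akt2_deleted (-1.60). The clusters differed here too, so the lists of this paragraph compare different mixtures of cells. One led by Wfdc18 and Ltf held 2.42% of the cells in Akt1_deleted on average and 24.9% in Akt2_deleted (0.152% in replicate 1). Across all groups it held 18.2 to 68.2% in libraries with over 5% haemoglobin UMIs and at most 4.86% in the others. Its difference was therefore not separated from haemoglobin content. The cluster led by Npy held 2.23% and 13.6% (33.6% in replicate 1). Glycolysis genes were lower in Akt2_deleted (median -0.43, 15 of 15 genes below 0, adjusted p 0.00304), led by Tpi1 (-0.75) and Hk2 (-0.65). Interferon response (median -0.62, adjusted p 0.00304; Bst2 -3.41, Ddx58 -0.65), MHC class I (-0.66, adjusted p 0.00365; H2-D1 -0.999, but H2-T23 1.13), hypoxia (-0.46, adjusted p 0.00517; Ndrg1 -0.78, Adm -1.59) and hormone-sensing genes (-1.52, adjusted p 0.00747; Cited1 -3.04, Prlr -1.06) were lower as well. So were epithelial adhesion (-0.36, adjusted p 0.00488; Krt19 -1.47, Cldn3 -0.49), mitosis (-0.27, adjusted p 0.00905; Ccnb1 -1.28, Cdk1 -0.74) and cholesterol synthesis genes (-0.30, adjusted p 0.0319; Hmgcs1 -1.002, Stard4 -1.04). Respiratory chain genes had a median of -0.14 (adjusted p 0.0112; Ndufs5 up, Uqcrq -0.75) and ribosomal protein genes of -0.25 (adjusted p 0.02; Rpl29 2.07, Rpl35a -1.17). Mesenchymal genes were higher in Akt2_deleted (median 0.55, adjusted p 0.0222), led by the matrix gene Sparc (2.50) while Mmp14 was lower (-0.84). Adjusted over the list alone, 2 hormone-sensing genes, 1 mesenchymal gene and 1 respiratory chain gene passed. H2-D1, H2-T23, Mmp14, Rpl29 and Rpl35a have near-identical copies and are uncertain, and with such genes left out the ribosomal (adjusted p 0.12) and cholesterol lists (0.0648) did not pass. None of the 12 calls held with an estimated correlation (adjusted p 0.31 to 0.734). Akt2_deleted replicates 2 and 3 had 21.02% and 26.6% haemoglobin UMIs, and without all libraries over 5%, which leaves 1 Akt2_deleted library, 2 lists passed, and none of the 12 kept its call: NFkB targets (median 0.75, higher) and respiratory chain genes in the other direction (median 0.27, adjusted p 0.00807). Mitosis genes then had a median of 0.23 (adjusted p 0.245), and cholesterol synthesis genes of 0.03 (adjusted p 0.707).

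Macrophage or monocyte-like cells were compared in the same way, first between the deletions. Mgl2, a lectin gene of alternatively activated macrophages, was 15.3 ± 26.5 CPM in Akt2_deleted and 440 ± 75.5 CPM in Akt1_deleted (log2 fold change -4.56 ± 1.09, SE, n = 3 each), and the lipoprotein lipase gene Lpl was 225 ± 102 against 1087 ± 325 CPM (-2.23 ± 0.51). The phosphatase gene Dusp1 (-2.02), the lectin receptor gene Clec4a2 (-1.31) and Shisa5 (-1.33) were lower, and the calcium-dependent kinase gene Camk1 (1.31), Sh3bgrl3 (1.002), Basp1 (1.498), Brd2 (1.47) and Rrp1 (1.20) were higher; none passed (adjusted p 0.507 to 0.53 in edgeR). Against PyMT_primary, where 4 of 5 libraries had at least 20 such cells, Akt2_deleted had lower Clec4a2 (-1.65), the lysosomal lipase gene Lipa (-1.11), the oxidase subunit gene Ncf4 (-1.62), Dusp1 (-1.68) and Shisa5 (-1.19). The chaperone gene Hsp90aa1 (1.75), the lysosomal gene Cd63 (1.14), Cox20 (1.53), Atp6v1a (1.53) and Rpl31 (2.58) were higher in Akt2_deleted. Akt1_deleted had higher Hsp90aa1 (1.51), Hnrnpf (1.72), Rpl31 (2.27), Rpl11 (2.38) and Rpl35a (1.75) and lower Hal (-1.90), Apbb1ip (-1.06), Camk1 (-0.97), Ncf4 (-1.16) and H2-Eb1 (-5.41), a class II gene that ranged from 97.4 to 17750 CPM over PyMT_primary. Rpl11, Rpl35a, Cd63 and Cox20 have near-identical copies and are uncertain. No gene passed in edgeR: 0 of 992 for Akt1_deleted against PyMT_primary (95 at an unadjusted p under 0.05, 1 by DESeq2), 0 of 992 for Akt2_deleted against PyMT_primary (93 and 0) and 0 of 992 between the deletions (86 and 0). The cells lay in different proportions in the clusters of the class: one led by Retnla and Lyz1 held 47 of 157 cells in Akt1_deleted, 6 of 90 in Akt2_deleted and 146 of 485 in PyMT_primary, and one led by C1qa and Apoe 84, 70 and 204 of them, so changes within a kind of macrophage were not separated from shifts between kinds. Without PyMT_primary replicate 5 the counts against PyMT_primary were 51 for Akt1_deleted and 45 for Akt2_deleted.

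In the lungs, the tumour epithelial-like cells were compared with those of the primary tumours to see what differed at the metastatic site. The class II antigen presentation genes Cd74 and H2-Ab1, usually made by immune cells, were higher there: Cd74 by 4.24 ± 0.72 (SE) and H2-Ab1 by 3.23 ± 0.55 on the log2 scale (n = 2 against 5), and both lung libraries lay above every PyMT_primary library. The p53 target gene Phlda3 (2.67), the cell cycle inhibitor gene Cdkn2a (3.06) and the proteoglycan gene Srgn (2.13) were also higher. Fxyd6 (-3.87), Camk2n1 (-3.32), Maz (-4.28), Snord13 (-3.68) and Homer2 (-3.12) were lower. None of 9285 genes passed in edgeR (adjusted p 0.495 or above), 467 had an unadjusted p under 0.05, and DESeq2 called 2. Akt1 (0.22 ± 0.52) and Akt2 (0.38 ± 0.49) differed by less than their errors. The micro-metastasis held 22 such cells with 26508 UMIs, among them 4 of Cd74, 2 of H2-Ab1 and 0 of H2-Aa. Of the tumour epithelial-like cells, 68.1% of the macro-metastasis were in a cluster led by Csn2 and Csn1s1 that held 4.98% in PyMT_primary on average. In the micro-metastasis 68.2% were in another, led by Wfdc18 and Ltf, that held 15.9% there (up to 59.8% in a library). It held at most 4.86% in libraries without over 5% haemoglobin UMIs (35.5% in the micro-metastasis). Shifts between clusters of the tumour epithelial-like cells were not separated from changes within them. Immune transcripts were present in these cells too. The 16 macrophage or monocyte markers, class II genes aside, were at 1.66% of their level in macrophage or monocyte-like cells in the macro-metastasis, 1.24% in the micro-metastasis and 1.23% in PyMT_primary. Cd74 was at 2.88%, 1.20% and 0.128% of its level there. T cell markers summed to 43.8, 113 and 12.9 CPM in the tumour epithelial-like cells, so RNA from immune cells was not excluded as a part of these differences.

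MHC class II genes rose as a list in the lung (median log2 fold change 3.00, 5 of 5 genes above 0, adjusted p 7.85e-17 in camera), and 5 of 5 passed when adjusted over the list alone, with RNA from immune cells not excluded here either. MHC class I genes rose with them (median 1.96, 12 of 12 genes above 0, adjusted p 3.43e-10), 9 of them past the threshold when adjusted over the list alone, led by H2-Q7 (3.64) and the immunoproteasome gene Psmb9 (2.17). Interferon response genes rose (median 0.85, adjusted p 3.95e-06), led by the guanylate binding protein genes Gbp2 (2.27) and Gbp3 (1.90). NFkB targets (median 0.34, adjusted p 0.0115), neutrophil activation genes (0.65, adjusted p 0.0196) and myeloid attracting factors (0.41, adjusted p 0.0447) rose, with Il1b at 2.80, Tnfaip2 at 2.02, Bcl3 at 1.23, Icam1 at 1.78 and Ccl2 at 2.12. RNA from immune cells was not excluded for these lists, nor for MHC class I and interferon genes. A different strain background was not excluded for the MHC lists either. ER stress genes rose (0.25, adjusted p 0.0212; Sesn2 1.45, Psat1 1.02), and so did ribosomal protein genes (0.12, adjusted p 0.0018), although Rpl39 (-0.89) and Rpl22 (-0.69) fell. Immediate early genes were lower (-0.31, adjusted p 0.0446; Fosb -1.67, Fos -0.95), but without the micro-metastasis they were called higher (0.35, adjusted p 0.0117), and without libraries over 5% haemoglobin their median was 0.199 (adjusted p 0.259). Without the macro-metastasis the 22 cells left had 0 UMIs for 13 of 25 interferon, 3 of 12 MHC class I and 1 of 5 MHC class II genes, too few to decide the direction of these lists; 5 lists passed, MHC class II not among them (adjusted p 0.092), and without the micro-metastasis 19 did. None of the 9 calls held with an estimated correlation (adjusted p 0.175 to 0.74). With the class term, which leaves the macro-metastasis against replicate 5 and the micro-metastasis against replicates 1 to 4, MHC class II (median 2.56, adjusted p 2.75e-08), MHC class I (1.06, adjusted p 0.0024) and interferon genes (1.18, adjusted p 8.35e-04) stayed higher, and immediate early genes lower (-1.12, adjusted p 1.78e-04), and respiratory chain genes were newly called lower (-0.48, adjusted p 3.04e-04). Ribosomal protein (-0.37, adjusted p 0.66), NFkB (-0.26, adjusted p 0.465), ER stress (-0.14, adjusted p 0.755), neutrophil activation (0.11, adjusted p 0.216) and myeloid factor genes (-0.06, adjusted p 0.35) no longer passed. Rpl39 has near-identical copies.

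**Figure D4:**
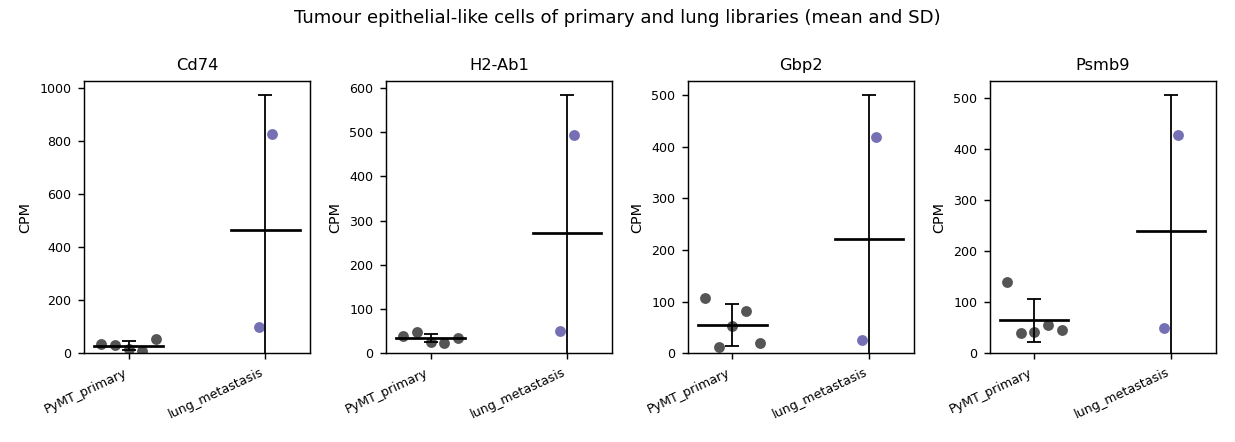
CPM per library (points) with the group mean and SD (black) in tumour epithelial-like cells of PyMT_primary (n = 5) and lung_metastasis (n = 2) for Cd74, H2-Ab1, Gbp2 and Psmb9. The higher lung point is the macro-metastasis, at 824 CPM for Cd74.

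The 2 lung libraries differed in composition, as values of 1 library per stage without a test. Tumour epithelial-like cells made up 9.65% of the micro-metastasis (exact binomial 95% interval 6.15 to 14.2%) and 61.6% of the macro-metastasis (58.3 to 64.8%). T cell-like cells made up 34.6% and 9.15%, neutrophil-like cells 15.4% and 0% (0 of 896 cells, which allows up to 0.335%), alveolar macrophage-like cells, the resident phagocytes of the lung, 18.0% and 2.23%, and macrophage or monocyte-like cells 7.89% and 25%. Against the primary tumours, alveolar macrophage-like and T cell-like cells were more frequent in both lung libraries and fibroblast-like cells (0.279 ± 0.395%) less frequent in both (exact permutation p 0.0952 each, the smallest that 2 against 5 libraries allow, adjusted 0.222).

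In tumour epithelial-like cells, the milk genes Csn2 (at least 22.0-fold) and Lao1 (19.9-fold, interval 3.55 to 785), the immediate early genes Fosb (20.6-fold, interval 3.68 to 813) and Atf3 (13.1-fold, interval 5.61 to 40.4), and Tob1 and Psme2 were among the 10 largest ratios of macro- over micro-metastasis, and Rpl10, Rpl23a, Rps12 and Rpl3 made up the rest. The 10 largest the other way were Gm43333 (32.6-fold), Hbb-bs, mt-Rnr1, mt-Rnr2, Eef1a1, Rpl41, mt-Nd2, Rpl23, Tmsb4x and Gm11942, from 1.93-fold up. The size rule was met by 1177 genes higher in the macro-metastasis and 32 higher in the micro-metastasis, which had far fewer UMIs. Only abundant transcripts could enter the list of the micro-metastasis, so the 2 lists are not comparable. The haemoglobin gene Hbb-bs, made by red cells, was 24.4-fold higher in the micro-metastasis, whose deposited UMIs were 35.5% haemoglobin. The libraries belong to different processing classes, and Rpl10, Rpl23a, Rps12, Psme2, Rpl3, Hbb-bs, Eef1a1, Rpl41 and mt-Nd2 have near-identical copies, so their ratios are uncertain.

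The log2 fold changes of Akt1_deleted and of Akt2_deleted, each against PyMT_primary, correlated over 8453 genes with Pearson's r of 0.484. Genes are not independent replicates, and both comparisons use the same controls. In 10 simulations of unchanged groups against those controls r averaged 0.321 (0.285 to 0.336), and the covariance was 0.188 against a simulated 0.089. Esr1 was the 1 gene called in both, against 0.1 in the simulations and 2.37e-04 for independent lists of the same sizes. All 6 deletion libraries are of class B and 4 of the 5 controls of class A, a difference the simulations do not carry, so the excess is not ascribed to the deletions. The 5 controls could not be split by class, as class B holds 1 of them.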

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

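All explanations of the first 3 patterns were thought of only after those patterns were seen, and the tests of the class difference, of near-identical copies and of the strain background were chosen only after the result was seen. For transgene reads the threshold of 0.5 and the condition on PyMT_primary were written before the values of that test were seen and the comparison with tumour genes after; the tests of the Akt2 chromosome segment and of other splits were written before their values were seen.

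Esr1 was higher in tumour epithelial-like cells of both deletion groups. Processing class as the whole cause is argued against by class B libraries without a deletion, since the lowest deletion library was 8.17 times the higher of those. Reads of the ERT2Cre transgene, which holds part of the receptor's coding sequence, may be counted as Esr1: its CPM in macrophage or monocyte-like and T cell-like cells of the deletion libraries was 0.558 of that in tumour epithelial-like cells (18 of 364590 UMIs, 49.4 CPM), where 6 abundant tumour genes had ratios of 0.021 to 0.0462. The same cells of PyMT_primary had 0 of 666989 UMIs, but those of the macro-metastasis, for which no deletion is named, had 32.5 CPM (11 of 338901). A response of the tumours to deletion or tamoxifen stays open as untested, since no library is labelled as having the transgene without deletion.

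Ribosomal protein genes were higher in tumour epithelial-like cells of both deletion groups. Processing class could account for this, as the list was 1.42 higher (median log2 ratio) in PyMT_primary replicate 5, of class B, than in replicates 1 to 4, of class A. In the same cells of the lung the macro-metastasis, of class B, was only 0.157 above the micro-metastasis, of class A, which held 22 such cells. For reads shared with near-identical copies, the 32 members without a copy had a median of 0.655 against 1.38 for the 49 with one in Akt1_deleted, and 0.59 against 1.05 in Akt2_deleted, so the part of the pattern outside copies cannot be told apart from the class difference. Within the class no rise was seen: with the class term the medians were 0.042 (Akt1_deleted) and -0.277 (Akt2_deleted), and in class B alone 0.035 and -0.264. Those fits compare the deletions with 1 PyMT_primary library, so an effect of Akt in either direction was not settled.

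Genes differed between Akt2_deleted and Akt1_deleted tumour epithelial-like cells. Within 10 Mb of Akt2, 3 of 137 genes had p under 0.01, against 97 of 8129 elsewhere (Fisher's exact p 0.23), too few to decide on a chromosome segment carried with the targeted locus. A different strain background of the groups may contribute. H2-Eb1, a class II gene that some mouse strains lack, was set against H2-Aa, another class II gene. The ratio was 21.9 times higher in the lowest Akt2_deleted library (30.5 to 40.04%) than in the highest Akt1_deleted library (0.8294 to 1.39%). In PyMT_primary the ratio ranged from 0.931 to 84.0%, so the ratio also varied within that group, and no other strain marker was tested. In the lung it was 40.8% in the micro-metastasis and 1.03% in the macro-metastasis. An effect of the deleted isoform stays open.

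Other splits of the libraries into groups of the same sizes were counted. For Akt1_deleted against PyMT_primary in tumour epithelial-like cells, 5 of 56 splits called at least 1 gene and the highest other called 105, so chance was not excluded. For Akt2_deleted against PyMT_primary, 6 of 56 called at least 2 and the highest other called 631, with PyMT_primary replicates 3 and 4 and Akt2_deleted replicate 1 in a group, so chance was not excluded, and a split calling so many points to a structure of the samples. In macrophage or monocyte-like cells the real count was 0 for each deletion against PyMT_primary, which 35 of 35 splits reach by construction, so that nothing follows for chance. The highest others were 59 and 47, both of them the split of class A (PyMT_primary replicates 2 to 4) from class B libraries, where the split by class gives the larger result; among class B libraries alone the real counts were 1 and 3. For gene lists against PyMT_primary, 40 of 56 splits reached the 6 of Akt1_deleted (highest other 13) and 43 of 56 the 5 of Akt2_deleted (highest other 12), so chance was not excluded. Between the deletions, 10 splits are too few: for genes 1 of 10 reached the real 1 in tumour epithelial-like cells (highest other 0), 10 of 10 the real 0 in macrophage or monocyte-like cells by construction (highest other 0), and for lists 2 of 10 reached the real 12 (highest other 13).

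In 7 of 44 sets of values tested, the gap between a single PyMT_primary library and the next was large against the range. For 2 of them the gap is 1 cell: alveolar macrophage-like cells were 0.133% in replicate 5 (1 of 750 cells) and erythroid-like cells 0.437% in replicate 1 (1 of 229), with 0% in the others, which any single cell would give. Endothelial-like cells were 1.012% in replicate 3 (next 0.284%) and neutrophil-like cells 0.877% in replicate 2 (next 0.189%). Pisd-ps1 was 23.7 CPM in replicate 5 (others from 38.98 CPM) and Ptprg 38.6 CPM in replicate 3 (next 30.1 CPM), both in tumour epithelial-like cells. Haemoglobin made up 24.8% of the UMIs of replicate 1 (next 5.35%). Chance flags about 1 in 20 groups where values are continuous, which shares with most libraries at 0 are not, and no explanation was tested.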

How the results depend on the processing

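The class, barcode, copy, merging, haemoglobin and Esr1 alternatives were chosen after seeing the data; the others were planned. The cause was not tested except where stated. The count of cell classes past the threshold was 0 under the alternatives run by exact permutation, which shows no stability: with 3 against 3 or 2 against 5 libraries, or with a library of the comparison left out, it could not be other than 0. In all, 3863 values of single genes, lists and shares kept their direction and their side of the threshold. A further 166 fell short of the threshold and 112 newly passed it, all in their main direction.

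Genes changed in tumour epithelial-like cells numbered 1 (Akt1_deleted against PyMT_primary), 2 (Akt2_deleted against PyMT_primary), 1 (Akt2_deleted against Akt1_deleted) and 0 (lung_metastasis against PyMT_primary) in edgeR, where 467 had an unadjusted p under 0.05 for the lung. With at least 200 genes and 300 UMIs per cell the first 2 were 3 and 4, and with at least 500 genes and 800 UMIs the first was 2. With no filter beyond 1 count they were 125, 94, 39 and 81 over 32168 genes tested (30382 for the lung), and DESeq2 gave 19, 29, 9 and 2. Sums thinned to the smallest library gave 0 for Akt1_deleted against PyMT_primary and 0 between the deletions, where fewer genes were tested. A fit of only the 2 groups gave 0 between the deletions, at least 50 cells per library 1 for the lung, and merged barcodes 2 for Akt1_deleted. The processing class term gave 0 for each deletion against PyMT_primary. With the barcode term as well the count was 0 for Akt2_deleted against PyMT_primary and 2 between the deletions. For Akt1_deleted it was 1, a lower gene, so Esr1 was not the gene called. Class B libraries alone gave 2 for each deletion against PyMT_primary, all lower, where the genes called without the restriction were higher, and 0 between the deletions, with 1 PyMT_primary library assumed to vary like the other groups. Without libraries over 5% haemoglobin (PyMT_primary replicates 1 and 2, Akt2_deleted replicates 2 and 3, lung_metastasis replicate 1), the 1 Akt2_deleted and 1 lung library left are assumed to vary like the other groups, and the count was 3 for Akt1_deleted and 10 for the lung.

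Leaving out each library in turn, the counts ranged from 1 to 64, 2 to 58, 0 to 1 and 0 to 1. Without PyMT_primary replicate 5, the class B library of its group, they were 64 and 58; without PyMT_primary replicate 1 the first was 3 and without Akt1_deleted replicate 1 it was 4. Between the deletions the count was 0 without Akt1_deleted replicate 1, 2 or 3 or Akt2_deleted replicate 1 or 3, and for the lung it was 1 without lung_metastasis replicate 1.

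In macrophage or monocyte-like cells, where edgeR called 0 (95, 93 and 86 at an unadjusted p under 0.05; DESeq2 1, 0 and 0), no filter beyond 1 count gave 36, 21 and 20 and class B libraries alone 1, 3 and 8. A fit of only the 2 groups gave 1 between the deletions. Left-out libraries gave 0 to 51 and 0 to 45, highest without PyMT_primary replicate 5, 1 without Akt2_deleted replicate 1 for Akt2_deleted against PyMT_primary, and 0 to 0 between the deletions. At 500 genes and 800 UMIs, and at 50 cells, the Akt2_deleted comparisons could not be fitted in these cells.

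With the replicate number as a replicate block, the count between the deletions was 7 in tumour epithelial-like and 22 in macrophage or monocyte-like cells. Same-numbered libraries correlated at 0.515, 0.0043 and 0.28 in their deviations, and Akt2_deleted replicate 2 correlated better with another number. Replicate 1 of both deletions has barcodes with an undetermined last base and replicates 2 and 3 do not, so the number also carries this barcode difference. No block was fitted against PyMT_primary or for the lung.

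Lists past the threshold numbered 6, 5, 12 and 9 in the same order as the genes. Alternatives that leave 1 library in a group assume, as for the genes, that it varies like the other groups. With an estimated correlation they were 0, 0, 0 and 0 in camera. No filter gave 12 for Akt1_deleted, 3 for Akt2_deleted and 19 for the lung; thinned sums gave 1, 3, 6 and 2. For the lung, 500 genes and 800 UMIs gave 4, at least 50 cells 19, the class term 5, class and barcode terms 5, and leaving out haemoglobin libraries 15, which also gave 2 between the deletions. For Akt2_deleted against PyMT_primary the class term gave 11 and class B alone 12. Left-out libraries gave 4 to 10 (10 without PyMT_primary replicate 4), 3 to 7 (3 without PyMT_primary replicate 4), 7 to 13 (7 without Akt1_deleted replicate 3 or Akt2_deleted replicate 2) and 5 to 19 (19 without lung_metastasis replicate 1, 5 without replicate 2).

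Ribosomal protein genes changed direction in the test or median: for Akt1_deleted against PyMT_primary the median was 0.042 with the class term, -0.119 with class and barcode terms and 0.035 in class B alone; for Akt2_deleted -0.277, -0.389 and -0.264; for the lung -0.367 with either term. In those of 0.042 and 0.035 the median was above 0 and camera's direction lower. Respiratory chain genes in Akt1_deleted were -0.114 with the class term and -0.126 in class B, and 0.266 between the deletions without haemoglobin libraries, where mitosis genes were 0.226. Hormone-sensing genes in Akt2_deleted were -0.805 with class and barcode terms, -0.566 in class B and -0.378 without Esr1, and mitochondrially encoded genes -0.092 without haemoglobin libraries, where camera's direction was higher. In the lung, NFkB targets had a median of 0.095 in thinned sums, where camera's direction was lower, and immediate early genes 0.349 with at least 50 cells and 0.199 without haemoglobin libraries.

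Without the macro-metastasis 22 lung cells are left, in which 13 of 25 interferon and 10 of 18 NFkB genes had 0 UMIs, so their medians are set by the prior count, and the others rest on few UMIs. Lung medians then ranged down to -1.08 for MHC class I (up to 2.74 without another library), -7.06 for NFkB (0.90), -6.66 for interferon (1.37), -2.23 for myeloid factors (0.93), -0.82 for ribosomal protein (0.58) and -1.38 for ER stress genes (0.84), and immediate early genes ranged from -3.37 to 0.35, the last without the micro-metastasis. Lung genes reversed without the macro-metastasis as well: Akt1 ranged from -8.22 to 0.61, Bcl3 from -0.94 to 1.73, Ccl2 from -7.25 to 2.66, Gbp2 from -1.13 to 3.00, Gbp3 from -0.47 to 2.45, H2-Q7 from -7.67 to 4.46, Icam1 from -8.09 to 2.61, Psat1 from -0.79 to 1.56 and Psmb9 from -0.30 to 2.88. Akt1, Ccl2, H2-Q7 and Icam1 had 0 UMIs in the micro-metastasis, so their fitted values depend on the prior count.

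Genes that changed sign otherwise had not passed: Akt1 in the lung was -0.076, -0.025 and -0.011 with at least 200 genes, at least 500 genes and merged barcodes. Akt1 in Akt2_deleted against PyMT_primary was 0.011 with the class term, 0.014 in class B and 0.206 without haemoglobin libraries. Parp14 in Akt1_deleted was 1.66 with the class term, 1.71 with class and barcode terms and 1.62 in class B. With class and barcode terms Rpl31 was -0.101 in Akt1_deleted, Rpl5 -0.173 in Akt2_deleted and H2-Eb1 in macrophage or monocyte-like cells 0.401 in Akt1_deleted.

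Akt1 CPM in Akt1_deleted minus PyMT_primary was -24.8 and ranged from -27.9 to -21.1 with a library left out, and Akt2 CPM in Akt2_deleted minus PyMT_primary was -10.7 and ranged from -12.4 to -7.93; with a library fewer every exact permutation p was at its floor for the group sizes, 0.0571 or 0.0952. Over all barcodes the Akt2 difference was -9.85 (exact permutation p 0.0714).

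Share differences near 0 changed sign. Macrophage or monocyte-like cells in Akt2_deleted minus PyMT_primary were 1.02 percentage points with at least 200 genes, 0.617 with at least 500 genes, 0.997 with classes from each cell's own markers, 8.17 over cells outside the epithelial classes and 0.00521 with merged barcodes. In the lung they were -5.34 outside the epithelial classes and -0.218 with merged barcodes. Luminal cells at 500 genes were 5.73 in Akt1_deleted minus PyMT_primary and -0.110 in Akt2_deleted minus Akt1_deleted. Left-out libraries gave ranges through 0: luminal -11 to 2.52 (Akt1_deleted minus PyMT_primary) and -3.35 to 7.57 (Akt2_deleted minus PyMT_primary), macrophage or monocyte-like -5.23 to 1.61, -4.36 to 5.72, -2.21 to 7.87 (between the deletions) and -6.01 to 11.1 (lung).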

Other observations

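A cluster of 486 cells matched no marker class and came almost wholly from Akt2_deleted replicate 1 (291 cells, 12.3% of its kept cells, exact binomial 95% interval 11.0161 to 13.7%) and PyMT_primary replicate 4 (188 cells, 8.88%, 7.71 to 10.2%), with 6 cells in PyMT_primary replicate 3 and 1 in the macro-metastasis. Its cells had cartilage genes, Cnmd at 689 CPM against 6.68 CPM in tumour epithelial-like cells, Ucma at 372 against 0.544 CPM, Otor at 367 against 1.09 CPM and Col2a1 at 335 against 1.32 CPM, while the cartilage genes Acan, at 0 CPM, and Sox9, at 81.1 against 268 CPM, were not higher. It also had the contractile genes Acta2 at 1828 against 11.4 CPM and Mylk at 144 against 8.55 CPM. The gene 1500015O10Rik was at 6252 against 43.3 CPM. Epcam was at 154 CPM against 2399 CPM and the fibroblast gene Col1a1 at 3.99 CPM against 5166 CPM in fibroblast-like cells. Median depth was 1188.5 UMIs, against 1000.5 in tumour epithelial-like cells of the 2 libraries. These genes were chosen after their values were seen.

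Among T cell-like cells, Cd8a had a UMI in 41.5% (exact binomial 95% interval 30.7 to 52.9%) of 82 cells of the macro-metastasis and 5.06% (1.40 to 12.5%) of 79 cells of the micro-metastasis, at median depths of 696 and 698 UMIs. Cd3e, a general T cell gene, also differed, at 31.7% and 13.9%, so the lower detection was not limited to Cd8a, and the libraries are of different processing classes. Nkg7, a gene of cytotoxic cells, had a UMI in 73.2% and 20.3%, and Tcf7, a gene of naive and memory T cells, in 6.10% and 27.8%. In tumour epithelial-like cells, which should lack these genes, the shares were 0%, 1.81% and 0.362% in the macro-metastasis (552 cells, median 1214.5 UMIs) and 0%, 4.55% and 4.55% in the micro-metastasis (22 cells, median 914.5 UMIs). In Akt1_deleted, 144 T cell-like cells had Cd8a in 13.2% (8.13 to 19.8%), Cd4 in 5.56%, Nkg7 in 34.0% and Gzmb in 3.47%, at a median of 624 UMIs. In PyMT_primary, 66 such cells had them in 16.7% (8.62 to 27.9%), 9.09%, 39.4% and 10.6%, at a median of 613 UMIs, with tumour epithelial-like cells under 0.6% for each gene in both groups. These genes were chosen after the classes were seen, and the shares pool cells over libraries without a test.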
